A study of Arabidopsis thaliana with 24 samples.

How the data were processed

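RNA-seq of roots of Arabidopsis thaliana Col-0 was analysed from 24 libraries in 8 groups of 3. Seedlings 7 days old had received Flavobacterium sp. 98 or a mock solution of 100 mM MgSO4 at the root tip, and roots were collected at 12 h, 48 h, 72 h and 6 d. Libraries were stranded (dUTP) and made from oligo(dT)-purified RNA. Groups were taken from the labels, and the table's columns were matched to samples by their titles.

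The table deposited by the authors gives signal, read counts per gene divided by a size factor per library, for 33055 genes in 24 libraries. Per the submitters' processing notes, reads were processed with Trimmomatic 0.39, HISAT2 2.2.1, SAMtools 1.11, featureCounts of Subread 2.0.1 and DESeq2. The genome build, the annotation and the strand setting of the read counting were not given in the sources used here, so genes that overlap a neighbour on the other strand are uncertain. The same holds for near-identical copies, since how reads matching several places were treated was not given. Gene symbols and types came from a reference table of assembly TAIR10.1, in which all 33055 locus codes were found, and no coordinates were used.

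The plan written before the data were examined was an edgeR test on counts, with limma on log2(value + pseudocount) if the table held no counts. It held normalised values, so limma became the main test. Dividing each library by its smallest step gave whole reads, within a tolerance of 0.01, for 605106 of 605107 values above 0. Recovered depth was 39655558 to 42221986 reads per library, with size factors of 0.918 to 1.053. Between 22002 and 22627 genes had 10 reads or more, and the top gene held 1.07% to 1.83% of reads. No pair of libraries in a group was identical or differed by less than sampling noise (chi-square per gene 5.78 to 46.7). An edgeR test on the recovered reads with TMM scaling, added after the data were seen, called 1832 genes higher and 1749 lower at 12 h, 3905 and 4252 at 48 h, 3868 and 4110 at 72 h, and 2841 and 2751 at 6 d.

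Genes were kept by filterByExpr over the 8 groups (minimum count 10, minimum total 15), which left 23329. Of the others, 3290 were at 0 in every library and 6436 had a value but were not tested. Values were tested as log2(value + 1) with limma 3.58.1 (trend), 1 coefficient per group and 16 residual degrees of freedom. The contrast at each time was inoculated minus mock at that time. The change of the response over time and the change of mock roots over time were each tested jointly over 3 contrasts, and then for each of the 6 pairs of times. P was adjusted by Benjamini-Hochberg and a gene passed at an adjusted p under 0.05. Overlaps between times used Fisher's exact test, 1-sided, over the tested genes.

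The 28 gene lists were written from textbook knowledge before the data were examined, with 634 entries and 628 distinct loci, 6 of them in more than 1 list. Of the entries 1 was moved to the locus the reference table gives for its symbol, 34 were kept by locus code and 0 were dropped. The lists were root hair initiation and growth, hair and non-hair cell patterning, abscisic acid and drought, auxin response, auxin synthesis and transport, cytokinin, ethylene, jasmonate, salicylate, pattern-triggered immunity, indole glucosinolate and camalexin, aliphatic glucosinolate, flavonoid and phenylpropanoid, iron deficiency, phosphate starvation, nitrate and nitrogen, sulfur deficiency, sugar starvation, hypoxia, heat shock, circadian clock, photosynthetic markers, cell cycle, meristem and root cap, endodermis and Casparian strip, suberin, xylem, and phloem. Each was tested with camera at a preset correlation between genes of 0.01, adjusted over 112 tests at the 4 times and over 168 between times. Camera passed 41 of the 112 and 81 of the 168. With the correlation estimated from the data 0 passed in either set, with 13 and 32 under 0.05 before adjustment and lowest adjusted p of 0.219 and 0.160. With fry 38 of the 41 passed. Members were counted by the test over all genes, and by limma p adjusted over the list alone.

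Genes were named by a rule fixed in advance. At each time it took the 10 largest increases and 10 largest decreases that passed, did not overlap between groups and had a mean CPM of at least 2, and the 4 members of each list with the smallest adjusted p. Where no member passed it took the 2 with the highest mean. It also took the 10 genes with the smallest joint p of a differing response. For 3 libraries against 3, groups fail to overlap by chance for 10% of genes that do not change.

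Replicate numbers were checked for pairing by correlating residuals of mock and inoculated libraries of the same number. At 72 h the correlation was 0.190, 0.307 and 0.512 for replicates 1, 2 and 3, and at the other times it lay between -0.085 and 0.025. All 3 were over 0.1 only at 72 h, so the numbers were taken to pair libraries at that time alone. Replicate 1 at 72 h did not correlate best with its own number. An offset of replicate 3 common to both treatments would alone raise all 3 correlations, so pairing of replicates 1 and 2 is not shown. The main test, fixed before, had no block, and a block was tried as an alternative.

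The steps were tested on simulated data with 23329 genes. Of 50 genes each changed 1.5-, 2-, 4- and 8-fold at 6 d, limma recovered 62%, 90%, 98% and 98%, with 7 false calls among 198. At 12 h, 48 h and 72 h, where nothing was changed, it called 0, 1 and 0 genes. Of 200 genes changed 3-fold between times in mock roots 97.5% were recovered. The changed list had an adjusted p of 1.92e-57 and 0 of 111 unchanged list tests passed. Simulated genes were independent and these lists were drawn at random, so false list calls among correlated members were not tested. In the real photosynthetic list the estimated correlation was 0.743. On the same simulated data edgeR called 200 with 8 false, and DESeq2 227 with 29 false. Each simulated gene had the same spread in all 24 libraries. In the real data the highest chi-square per gene between replicates was 34.24 at 12 h and 46.67 at 72 h. It was 16.94 at 48 h and 13.24 at 6 d. False calls at a time with a wider spread than the others were thus not tested.

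Alternatives fixed before the data were examined were edgeR with RLE scaling and DESeq2 on recovered reads, no filter and a filter at a mean CPM of 2, a replicate block, the 6 libraries of a time alone, leaving out each library, estimated correlation and fry. Added after the data were seen were edgeR with TMM scaling, values rescaled by TMM, pseudocounts of 0.5 and 5, a block within the 6 libraries of a time, leaving out both 72 h libraries numbered 3, and the photosynthetic marker mean as a covariate. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, statmod 1.5.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used. Reads themselves were not used here.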

Results

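Roots of Col-0 seedlings inoculated at the tip with Flavobacterium sp. 98, or mock treated, were compared at 12 h, 48 h, 72 h and 6 d, with 3 libraries per group and 24 libraries in all. Depth, recovered from the steps between the deposited values, was 39655558 to 42221986 reads per library. Values are normalised reads, given as mean ± SD over n = 3 libraries, or as a fold with its log2 and SE from limma. A fold is on the log2(value + 1) scale, which understates the change of genes near 0. The labels do not say that libraries of a group came from separate cultures, so p measures the spread between these samples, which may be technical. The tests, gene lists and rule for naming genes were fixed before the data were examined. Genes named by hand after the values were seen are marked as such.

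Inoculation changed 3683 of 23329 tested genes at 12 h (1874 higher, 1809 lower), 8151 at 48 h (3995 higher, 4156 lower), 7930 at 72 h (3813 higher, 4117 lower) and 5493 at 6 d (2558 higher, 2935 lower), at adjusted p under 0.05. Changes of 2-fold or more were more often decreases: 121 higher and 262 lower at 12 h, 301 and 893 at 48 h, 416 and 931 at 72 h, and 321 and 370 at 6 d. At 12 h a fit to its 6 libraries alone left 551 higher and 671 lower, leaving out inoculated replicate 1 left 1118 higher and 1071 lower, and leaving out mock replicate 2 left 1188 higher. The main fit pools the spread over all 24 libraries, which may be too small for 12 h. At 72 h its 6 libraries alone left 2424 higher and 2581 lower, or 3518 and 3796 with replicate number as a block. At 6 d leaving out inoculated replicate 1 left 1629 higher.

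**Figure D1:**
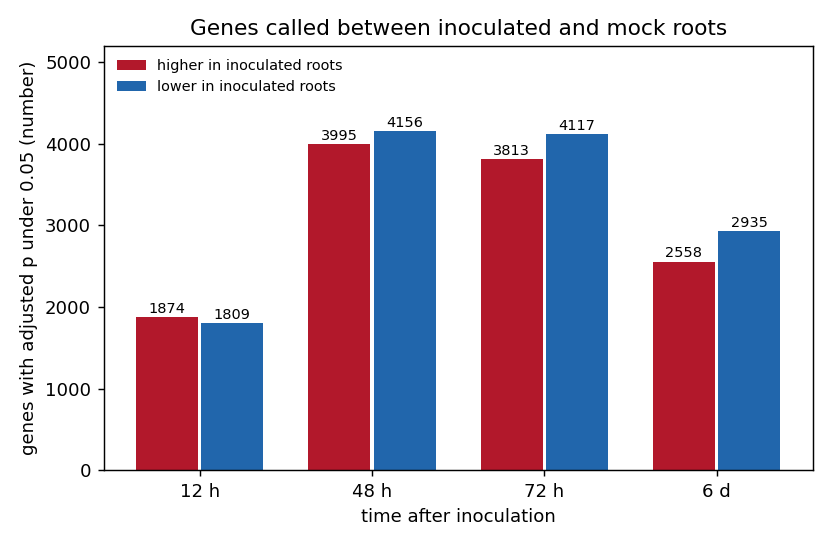
Genes higher and lower in inoculated than in mock roots at each time (limma, adjusted p under 0.05, 23329 genes tested, n = 3 libraries per group).

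Genes of root hair growth rose late. PRP1, which encodes a proline-rich wall protein of root hairs, went from 615.9 ± 377 in mock to 2705 ± 413 in inoculated roots at 72 h (4.88-fold, log2 2.29, SE 0.27, adjusted p = 1.75e-06) and from 1299 ± 230 to 5579 ± 289 at 6 d (4.33-fold, log2 2.11, SE 0.27, adjusted p = 2.04e-05), n = 3 each. XTH26, a wall-loosening xyloglucan enzyme gene active in hairs, was higher at every time: 5.08-fold at 12 h (log2 2.34, SE 0.41), 8.40-fold at 48 h (log2 3.07, SE 0.41), 19.4-fold at 72 h (log2 4.28, SE 0.41) and 6.37-fold at 6 d (log2 2.67, SE 0.41). PRX44, a peroxidase gene needed for hair growth, rose 1.70-fold at 12 h, 1.83-fold at 48 h, 2.28-fold at 72 h and 2.26-fold at 6 d. RHS13, a root hair-specific gene, rose 2.44-fold at 48 h, 2.89-fold at 72 h and 2.68-fold at 6 d, and the peroxidase gene RHS18 rose 2.97-fold at 6 d (log2 1.57, SE 0.20). Not every hair gene rose at first: at 12 h RHS8 was 2.16-fold lower and SCN1, whose product restricts hair initiation to one site per cell, was 1.31-fold lower.

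Of 49 root hair genes, 7 rose and 10 fell at 12 h, with 32 not passing (8 and 10 adjusted over the list alone). At 48 h 16 rose and 12 fell, with 21 not passing (18 and 13 adjusted over the list alone), at 72 h 30 rose and 6 fell, with 13 not passing (30 and 8 adjusted over the list alone), and at 6 d 34 rose and 0 fell, with 15 not passing (35 and 0 adjusted over the list alone). The list median was log2 -0.03 at 12 h, 0.21 at 48 h, 0.65 at 72 h and 0.82 at 6 d. In camera, with its preset correlation between genes, the list passed at 72 h (adjusted p = 1.72e-05) and 6 d (adjusted p = 1.23e-19). It did not with a correlation estimated from the data (adjusted p = 0.576 with an estimated correlation at 72 h, adjusted p = 0.307 with an estimated correlation at 6 d). At 48 h it did not pass (adjusted p = 0.121), but did without inoculated 48 h replicate 3 (0.30, adjusted p = 0.0232) and without mock 72 h replicate 3 (0.21, adjusted p = 0.0449). The rise was larger at 6 d than at 12 h by a median of 0.86 (camera adjusted p = 6.04e-15; adjusted p = 0.238 with an estimated correlation).

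**Figure D2:**
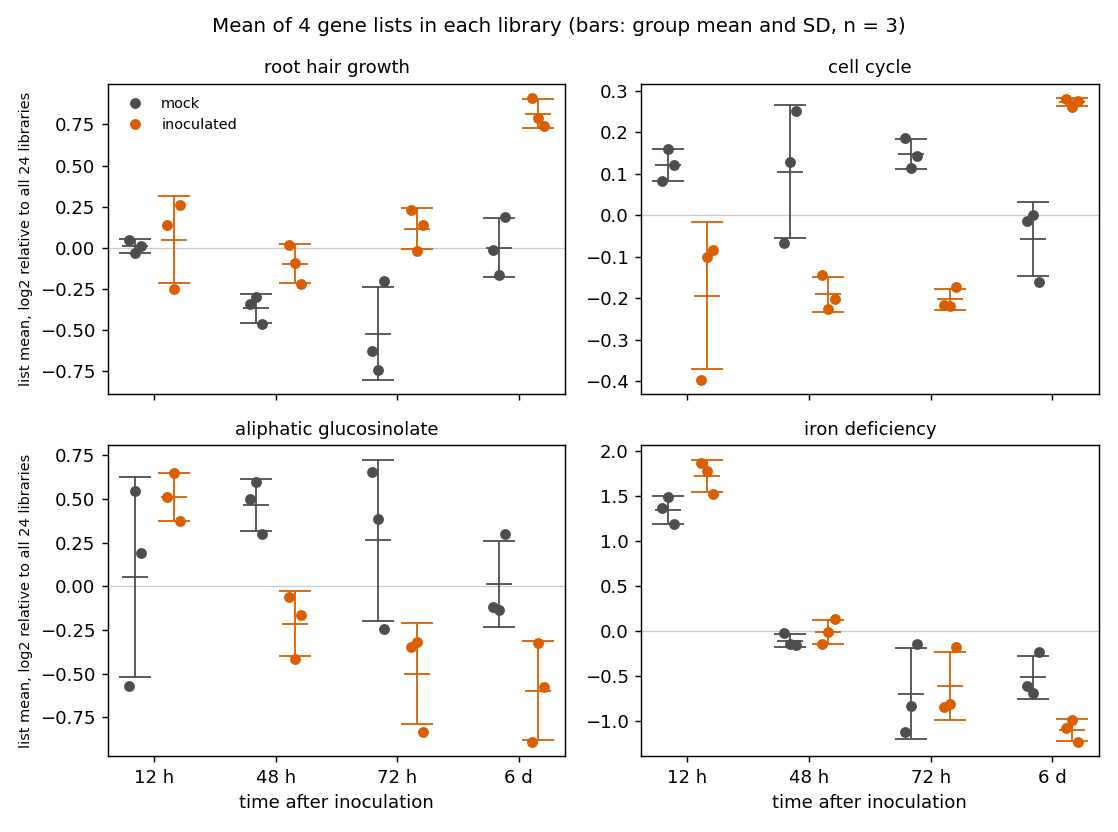
Mean of 4 gene lists in each of the 24 libraries, on a log2 scale relative to all libraries. Bars give group mean and SD, n = 3 libraries.

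Among genes that set hair against non-hair cell fate, 7 of 13 fell and 0 rose at 12 h, with 6 not passing (7 and 0 adjusted over the list alone): EGL3, a bHLH gene of non-hair fate, fell 2.17-fold (log2 -1.12, SE 0.16) and MYB23, a MYB gene that reinforces it, fell 2.34-fold (log2 -1.23, SE 0.25). The list median was -0.68 (camera adjusted p = 0.0101; adjusted p = 0.307 with an estimated correlation). At 72 h 4 fell, among them TTG2 (2.24-fold, log2 -1.16, SE 0.15) and SCM, a receptor gene that positions hair cells (1.39-fold, log2 -0.48, SE 0.08), and the list did not pass in camera (median -0.08, adjusted p = 0.116). At 48 h 3 fell (adjusted p = 0.162) and at 6 d 2 rose and 2 fell. With fry, a rotation test of a list by itself, it passed at 48 h (adjusted p = 0.00124) and 72 h (adjusted p = 8.91e-05).

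Genes of abscisic acid and drought response went in both directions. NCED3, which encodes the enzyme that limits abscisic acid synthesis, was 2.29-fold lower at 12 h (log2 -1.20, SE 0.24), fell from 423 ± 101 to 98.14 ± 18.9 at 48 h (4.25-fold, log2 -2.09, SE 0.24, adjusted p = 1.37e-06, n = 3) and was 3.84-fold lower at 72 h (log2 -1.94, SE 0.24). The receptor gene PYL5 was 1.67-fold higher at 12 h, 1.59-fold higher at 48 h and 1.63-fold higher at 72 h, then 1.36-fold lower at 6 d. Among members induced by drought or cold, KIN2 fell 2.44-fold at 48 h, COR47 1.84-fold at 72 h, and the NAC gene RD26 2.32-fold at 48 h, 2.23-fold at 72 h and 1.65-fold at 6 d. At 6 d CYP707A3, an abscisic acid breakdown gene, rose 2.05-fold. Of 42 members 5 rose and 4 fell at 12 h, 6 and 13 at 48 h, 6 and 16 at 72 h, and 3 and 8 at 6 d (5 and 4, 6 and 14, 6 and 16, 3 and 9 adjusted over the list alone). The list as a whole passed in camera at no time (medians 0.07, -0.16, -0.19 and -0.20; camera adjusted p = 0.569, 0.187, 0.149 and 0.216). With fry it passed at 72 h (adjusted p = 0.0315).

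At 12 h some genes of nitrate and sulfate uptake and of the iron deficiency response rose. NRT2.1, a high-affinity nitrate transporter gene, rose from 104.7 ± 13.6 to 1102 ± 628 (9.03-fold, log2 3.17, SE 0.65, adjusted p = 0.00221, n = 3), and SULTR1;2, the main root sulfate transporter gene, from 12730 ± 1620 to 38350 ± 8640 (2.98-fold, log2 1.58, SE 0.16, adjusted p = 1.61e-06). SDI1, a gene induced by sulfur shortage, rose 5.14-fold (log2 2.36, SE 0.41), FIT, the bHLH regulator of iron uptake, 2.2-fold (log2 1.14, SE 0.14), and RNS1, a ribonuclease gene induced by phosphate shortage and wounding, 5.45-fold (log2 2.45, SE 0.21). The largest decreases included AT5G62330 (20.5-fold, log2 -4.36, SE 0.24), the arabinogalactan protein gene AGP30 (9.58-fold, log2 -3.26, SE 0.31), the signalling peptide gene CLE5 (7.91-fold, log2 -2.98, SE 0.34), the pectin methylesterase inhibitor gene AT5G62340 (6.48-fold, log2 -2.70, SE 0.24) and MLO14 (5.13-fold, log2 -2.36, SE 0.27).

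By list at 12 h, 10 of 23 nitrate and nitrogen genes rose and 0 fell (13 and 1 adjusted over the list alone), with the ammonium transporter genes AMT1;2 (1.79-fold) and AMT1;1 (1.74-fold) and the nitrate reductase gene NIA2 (1.79-fold). Their median was 0.33 (camera adjusted p = 8.52e-06; adjusted p = 0.307 with an estimated correlation). Of 31 iron deficiency genes 10 rose and 0 fell (11 and 0 adjusted over the list alone), median 0.50 (adjusted p = 5.37e-05; adjusted p = 0.366 with an estimated correlation). Of 27 phosphate starvation genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), with the phosphate transporter gene PHT1;1 at 1.87-fold and PHF1 at 1.53-fold. That list passed at a median of 0.08 (adjusted p = 0.0281; adjusted p = 0.523 with an estimated correlation), but not without inoculated replicate 1 (adjusted p = 0.0987), and its median ranged from 0.03 without inoculated replicate 2 to 0.15 without inoculated replicate 3 and 0.17 without mock replicate 2. Of 15 sulfur deficiency genes 5 rose and 1 fell (5 and 2 adjusted over the list alone), among them SULTR1;1 at 3.38-fold. Their median was 0.32 (adjusted p = 0.0194; adjusted p = 0.644 with an estimated correlation) and the list did not pass without inoculated replicate 1 (median 0.12, adjusted p = 0.146). Without mock replicate 1 the median was 0.19. The mock solution was 100 mM MgSO4, and the labels do not state the solution that carried the bacteria.

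Of 16 clock genes 3 rose and 0 fell at 12 h, and the list did not pass in camera (median 0.38, adjusted p = 0.174). It did pass in camera with a replicate block (0.0105) or without both 72 h libraries numbered 3 (0.0126), and with fry (0.00655). GI, an evening clock gene, was at 128 to 717.6 in mock and 997.7 to 1606 in inoculated roots (3.87-fold, log2 1.95, SE 0.37), but did not pass with the 6 libraries of 12 h alone (adjusted p = 0.0686). PRR7 rose 2.14-fold (log2 1.1) and LNK1 2.79-fold. Neither passed without mock replicate 1 (PRR7 log2 0.62, adjusted p = 0.0845; LNK1 adjusted p = 0.103) or without inoculated replicate 2 (0.0720 and 0.0750), and PRR7 did not with the 6 libraries alone (0.133). The morning gene CCA1 did not pass (adjusted p = 0.648), at 5588 to 7260 in mock and 8924 to 10620 in inoculated roots. With 3 libraries against 3, chance leaves the groups of 10% of genes without overlap. The iron reductase gene FRO2, known to cycle over the day, did not pass either (adjusted p = 0.609), at 27290 to 48240 and 47620 to 84310. The p of CCA1 and FRO2 rest on a spread pooled over all 24 libraries, which includes the wide spread of both genes within each 72 h group, so a difference at 12 h is not excluded. The labels do not give the hour of harvest, so the higher iron and nitrate lists at 12 h were not separated from a difference in clock state.

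Signalling lists also moved at 12 h. ACS7, an ethylene synthesis gene, rose 2.82-fold (log2 1.49, SE 0.19), and 7 of 21 ethylene genes rose with 0 falling (7 and 0 adjusted over the list alone). The ethylene median was 0.17 (camera adjusted p = 0.0154; adjusted p = 0.307 with an estimated correlation; 0.0626 without inoculated replicate 1). Of 37 pattern-triggered immunity genes 6 rose and 0 fell (8 and 0 adjusted over the list alone), with WRKY11 at 1.52-fold and the receptor-like kinase gene BIK1 at 1.29-fold. Their median was 0.21 (adjusted p = 0.0181; adjusted p = 0.644 with an estimated correlation), and the list did not pass without mock replicate 2 (0.150), inoculated replicate 1 (0.225) or inoculated replicate 2 (0.0520), nor with fry (0.0916). The median was 0.09 without inoculated replicate 1 and 0.33 without inoculated replicate 3. Of 20 hypoxia genes 5 rose and 0 fell (5 and 0 adjusted over the list alone), led by the ERF regulator HRE2 (3.83-fold, log2 1.94, SE 0.26). Their median was 0.21 (adjusted p = 0.0200; adjusted p = 0.474 with an estimated correlation; 0.0609 without mock replicate 1 and 0.0719 without inoculated replicate 2).

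Cell division genes fell at 12 h: 15 of 31 fell and 0 rose (20 and 0 adjusted over the list alone), among them the cytokinesis kinesin gene HIK (1.44-fold, log2 -0.52, SE 0.10), at a median of -0.31 (camera adjusted p = 2.35e-08; adjusted p = 0.366 with an estimated correlation). Of 13 sugar starvation genes 4 fell and 0 rose (5 and 0 adjusted over the list alone), with DIN10 1.73-fold and the dormancy gene DRM1 1.58-fold lower. Their median was -0.52 (adjusted p = 0.00395; adjusted p = 0.523 with an estimated correlation; 0.0589 with fry). Of 17 aliphatic glucosinolate genes 6 rose and 0 fell (8 and 0 adjusted over the list alone), with the chain elongation genes MAM3 (1.73-fold) and BCAT4 (1.63-fold), median 0.42 (adjusted p = 0.000166; adjusted p = 0.508 with an estimated correlation). Mock replicate 1 at 12 h stood apart in the green tissue markers: the list of 29 photosynthetic genes averaged -2.71 in it, against 1.304 and 0.61 in the other mock libraries and 0.40 to 0.65 in the inoculated ones. The aliphatic list mean in the same library was -0.57, against 0.55 and 0.19, and without it the aliphatic median at 12 h was 0.21. No photosynthetic gene passed at 12 h (list median 0.70, camera adjusted p = 0.0740, or 0.0196 with a replicate block). That median was -0.40 without mock replicate 1 (adjusted p = 0.0497), 1.48 without mock replicate 2 (adjusted p = 4.13e-06) and 1.08 without mock replicate 3 (adjusted p = 0.00333).

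At 48 h the largest increases included genes of detoxification and stress. The MATE efflux gene AT2G04050 rose from 11.04 ± 6.99 to 465.6 ± 117 (43.8-fold, log2 5.45, SE 0.67, adjusted p = 2.74e-06, n = 3); reads of it and its neighbouring copy AT2G04070 are hard to tell apart. The mitochondrial CHCH-domain gene AT5G09570 rose 39.7-fold (log2 5.31, SE 0.47), the glucosyltransferase gene DOGT1 22.4-fold (log2 4.49, SE 0.66), the peroxidase gene AT1G49570 12.9-fold (log2 3.69, SE 0.33), the peptide transporter gene PTR3 7.66-fold (log2 2.94, SE 0.22) and the DNA damage induced gene GMI1 7.15-fold (log2 2.84, SE 0.18). MRN1, which makes the triterpene marneral, fell from 1495 ± 440 to 71.76 ± 27.7 (20.9-fold, log2 -4.38, SE 0.41, adjusted p = 1.21e-07), CLE5 fell 14.4-fold (log2 -3.85, SE 0.34), and AT5G62330 14-fold (log2 -3.81, SE 0.24).

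Cytokinin genes fell at 48 h. ARR7, a cytokinin-induced response regulator gene, fell from 1031 ± 80.5 to 291.2 ± 30.1 (3.54-fold, log2 -1.82, SE 0.13, adjusted p = 3.81e-09, n = 3), and ARR6 (1.67-fold), ARR9 (1.66-fold) and the trans-zeatin synthesis gene CYP735A2 (2.23-fold) fell with it. Of 23 cytokinin genes 14 fell and 0 rose (14 and 1 adjusted over the list alone), median -0.54 (camera adjusted p = 2.38e-05; adjusted p = 0.219 with an estimated correlation). The auxin-induced GH3.3, which encodes an auxin-conjugating enzyme, rose 5-fold (log2 2.32, SE 0.25) and GH3.2 2.62-fold (log2 1.39, SE 0.23). Of 25 auxin response genes 8 rose and 2 fell (8 and 2 adjusted over the list alone), median 0.24 (adjusted p = 0.0350; adjusted p = 0.511 with an estimated correlation), but the list did not pass without mock replicate 2 (0.0920) or inoculated replicate 3 (0.102), and its median was 0.37 without inoculated replicate 1. Of 15 auxin synthesis and transport genes 0 rose and 4 fell. The influx carrier gene AUX1 fell 1.37-fold and the auxin synthesis gene TAR2 1.56-fold.

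Hypoxia genes rose: HRE1 2.07-fold (log2 1.05, SE 0.10), HRE2 5.13-fold (log2 2.36, SE 0.26) and the fermentation gene ADH1 3.83-fold (log2 1.94, SE 0.24). Of 20 members 14 rose and 1 fell (14 and 1 adjusted over the list alone), median 0.64 (camera adjusted p = 9.39e-05; adjusted p = 0.307 with an estimated correlation). Defence metabolism fell. Of 24 indole glucosinolate and camalexin genes 15 fell and 0 rose (17 and 0 adjusted over the list alone), with the regulator MYB34 1.56-fold (log2 -0.65, SE 0.07) and CYP81F4 1.63-fold lower, median -0.60 (adjusted p = 1.81e-05; adjusted p = 0.307 with an estimated correlation). Of 17 aliphatic glucosinolate genes 12 fell and 0 rose (12 and 0 adjusted over the list alone), with CYP79F2 2.38-fold lower, median -0.71 (adjusted p = 8.52e-06; adjusted p = 0.427 with an estimated correlation). Of 26 jasmonate genes 10 fell and 1 rose (10 and 1 adjusted over the list alone), with the repressor gene JAZ7 4.13-fold and the synthesis gene OPR3 1.53-fold lower, median -0.36 (adjusted p = 0.0114; adjusted p = 0.307 with an estimated correlation). Of 16 flavonoid and phenylpropanoid genes 8 fell and 0 rose (8 and 0 adjusted over the list alone), with 4CL1 1.53-fold and F3'H 2.31-fold lower, median -0.31 (adjusted p = 0.00373; adjusted p = 0.366 with an estimated correlation). That median was -0.51 without mock replicate 3 and -0.50 without inoculated replicate 3.

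Suberin genes fell at 48 h: MYB41, a regulator that switches suberin synthesis on, went from 278.4 ± 27.8 to 56.49 ± 21.7 (5.12-fold, log2 -2.35, SE 0.30, adjusted p = 4.40e-06, n = 3), the exporter gene ABCG6 fell 2.48-fold and the elongase gene KCS2 2.09-fold. Of 18 members 13 fell and 1 rose (13 and 1 adjusted over the list alone), median -0.58 (camera adjusted p = 1.22e-06; adjusted p = 0.366 with an estimated correlation). Of 31 cell cycle genes 15 fell and 1 rose (18 and 1 adjusted over the list alone), with the Aurora kinase gene AUR2 1.69-fold and the cyclin gene CYCB1;4 1.55-fold lower, median -0.35 (adjusted p = 0.000192; adjusted p = 0.523 with an estimated correlation), or -0.23 without mock replicate 3.

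At 72 h many of the changes seen at 48 h were present. MRN1 fell from 1515 ± 432 to 38.72 ± 23.8 (44.6-fold, log2 -5.48, SE 0.41, adjusted p = 7.71e-09, n = 3), CLE5 fell 19-fold (log2 -4.25, SE 0.34) and the terpenoid cyclase gene AT3G32030 13.1-fold (log2 -3.71, SE 0.26). FLA6, a fasciclin-like wall protein gene, rose from 108.1 ± 101 to 908.5 ± 125 (10.8-fold, log2 3.44, SE 0.40, adjusted p = 1.58e-06), DOGT1 rose 12.9-fold (log2 3.69, SE 0.66), and the cupin gene AT5G38940 8.68-fold (log2 3.12, SE 0.20). BHLH100, an iron deficiency regulator, was listed at 0 in all 3 inoculated libraries, with a mock mean of 14.82. Of the genes that changed, 2823 were higher and 3011 lower at both 48 h and 72 h, where independent changes would give 653 and 733.4. Of those changing in opposite directions, 1 was higher then lower and 5 were lower then higher. Fold changes correlated across genes at r = 0.764, where genes are not independent replicates. The test of whether the response differed between the times called 2 genes, and 10 lists in camera (0 with an estimated correlation). Among those lists the median response moved by 0.34 for root hair (adjusted p = 4.76e-11), 0.23 for suberin (adjusted p = 6.61e-07) and 0.18 for xylem (adjusted p = 3.71e-06).

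Endodermis genes fell at 48 h in part and further at 72 h. At 48 h 5 of 10 fell and 1 rose (6 and 1 adjusted over the list alone, in the same order), median -0.34, and the list did not pass in camera (adjusted p = 0.0566). It passed there with a replicate block (0.0203), with fry (0.0396) and when any of 8 single libraries was left out, at 0.0272 without inoculated 48 h replicate 2 to 0.0498 without mock 12 h replicate 1. At 12 h, where 2 fell (median -0.02, adjusted p = 0.180), it passed without inoculated 12 h replicate 1 (0.00440) or mock 12 h replicate 2 (0.0482). At 72 h CASP4 and CASP1, which build the Casparian strip, fell 2.2-fold (log2 -1.14, SE 0.14) and from 10750 ± 128 to 5933 ± 920 (1.83-fold, log2 -0.87, SE 0.13, adjusted p = 2.11e-05, n = 3). Of 10 endodermis and Casparian strip genes 9 fell and 1 rose (9 and 1 adjusted over the list alone), with the peroxidase gene PER64 1.89-fold lower, median -0.69 (camera adjusted p = 9.39e-05; adjusted p = 0.366 with an estimated correlation). The decrease exceeded that at 48 h by a median of -0.43 (adjusted p = 6.52e-06; adjusted p = 0.238 with an estimated correlation). Of 18 suberin genes 10 fell and 1 rose (10 and 1 adjusted over the list alone), with MYB92 1.48-fold and MYB53 2.25-fold lower, median -0.33 (adjusted p = 0.00457; adjusted p = 0.590 with an estimated correlation). Of 31 cell cycle genes 17 fell and 2 rose (18 and 2 adjusted over the list alone), with the cytokinesis gene KNOLLE 1.69-fold lower, median -0.34 (adjusted p = 2.65e-05; adjusted p = 0.506 with an estimated correlation).

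Most hormone and defence lists that passed at 48 h passed in the same direction at 72 h. The flavonoid and phenylpropanoid list did not pass at 72 h, with 7 genes lower and 1 higher (median -0.32, adjusted p = 0.149; 0.0301 with fry). The cytokinin oxidase gene CKX4 fell 3.74-fold (log2 -1.90, SE 0.22), and 11 of 23 cytokinin genes fell with 1 rising (12 and 1 adjusted over the list alone), median -0.37 (camera adjusted p = 0.00178; adjusted p = 0.307 with an estimated correlation). GH3.3 rose 6.71-fold (log2 2.75, SE 0.25) and 8 of 25 auxin response genes rose with 3 falling (9 and 3 adjusted over the list alone), median 0.32 (adjusted p = 0.0255; adjusted p = 0.506 with an estimated correlation; 0.0519 without inoculated replicate 1), or 0.15 without mock replicate 2. HRE2 rose 4.01-fold, and 12 of 20 hypoxia genes rose with 1 falling (13 and 1 adjusted over the list alone), median 0.67 (adjusted p = 0.000391; adjusted p = 0.307 with an estimated correlation). MYB34 fell 1.85-fold and CYP79B2, the entry enzyme to indole glucosinolates, 1.99-fold. Of 24 indole defence genes 13 fell and 0 rose (15 and 0 adjusted over the list alone), median -0.58 (adjusted p = 3.57e-05; adjusted p = 0.307 with an estimated correlation). Of 17 aliphatic glucosinolate genes 14 fell and 0 rose (15 and 0 adjusted over the list alone), with the sulfotransferase gene SOT17 1.98-fold lower, median -0.71 (adjusted p = 5.82e-06; adjusted p = 0.427 with an estimated correlation). Of 26 jasmonate genes 10 fell and 1 rose (10 and 1 adjusted over the list alone), with the jasmonate marker VSP1 3-fold lower (log2 -1.58, SE 0.17), median -0.35 (adjusted p = 0.0172; adjusted p = 0.307 with an estimated correlation).

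Immune and salicylate genes rose in part at 72 h. ALD1, which makes pipecolic acid, rose 4.19-fold (log2 2.07, SE 0.24) and WRKY54 2.18-fold, while the salicylate precursor exporter gene EDS5 fell 2.13-fold (log2 -1.09, SE 0.09). Of 20 salicylate genes 8 rose and 2 fell (8 and 2 adjusted over the list alone), and of 37 pattern immunity genes 11 rose and 2 fell (13 and 2 adjusted over the list alone), with WRKY11 at 1.63-fold and the peroxidase gene PER71 at 1.95-fold. Neither list passed in camera (salicylate median 0.25, adjusted p = 0.0597; immunity median 0.16, adjusted p = 0.0795). With replicate number as a block, taken here to pair libraries at 72 h, both passed (0.0403 and 0.0414), as did the nitrate list (0.0455) and the clock list (0.0336). With fry salicylate passed (0.0114). Leaving out mock 72 h replicate 2 also let both pass (salicylate 0.0493, immunity 0.0489), as did leaving out inoculated 72 h replicate 2 (0.0408 and 0.0316). Salicylate further passed without inoculated 72 h replicate 3 (0.0463) or inoculated 12 h replicate 3 (0.0466).

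The 72 h libraries fell into a pair of clock states. The morning gene CCA1 was at 109.5 and 148.8 in mock replicates 1 and 2 and 64.97 and 75.45 in the inoculated ones, against 1178 and 1230 in replicate 3 of each treatment. The evening gene TOC1 ran the other way, with 5673, 6492, 5348 and 5399 against 1564 and 1976. FRO2 was at 518.3, 1080, 2259 and 3192 against 19870 and 26790. Both treatments were present in each state, so the comparison within 72 h was balanced. With replicates 1 and 2 alone 3556 genes were higher and 4072 lower. Of the genes passing with all 3 libraries, 98.7% had the same sign in the replicate 3 pair, which is partly built in because that pair was in the fit. Among genes not passing, 61.6% had the same sign in replicates 1 and 2 as in the replicate 3 pair. Across genes the correlation of these was r = 0.565. The root hair median was 0.72 in replicates 1 and 2 and 0.36 in the replicate 3 pair, endodermis -0.73 and -0.53, suberin -0.24 and -0.45, hypoxia 0.76 and 0.33, and auxin response 0.43 and 0.05. Aliphatic glucosinolate gave -0.88 and -0.48, indole defence -0.61 and -0.44, cytokinin -0.42 and -0.27, cell cycle -0.44 and -0.31, and jasmonate -0.36 and -0.30. The clock list gave -0.39 and -0.06, with 6 of 16 genes lower and 0 higher in replicates 1 and 2. The replicate 3 libraries also held fewer green transcripts: the photosynthetic mean was -1.638 in mock and -0.955 in inoculated roots, against -0.192 to 1.206 in replicates 1 and 2, and RBCS1A was at 518.7 and 389, against 2180 to 8200. CCA1, TOC1, FRO2 and RBCS1A were named after their values were seen.

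**Figure D3:**
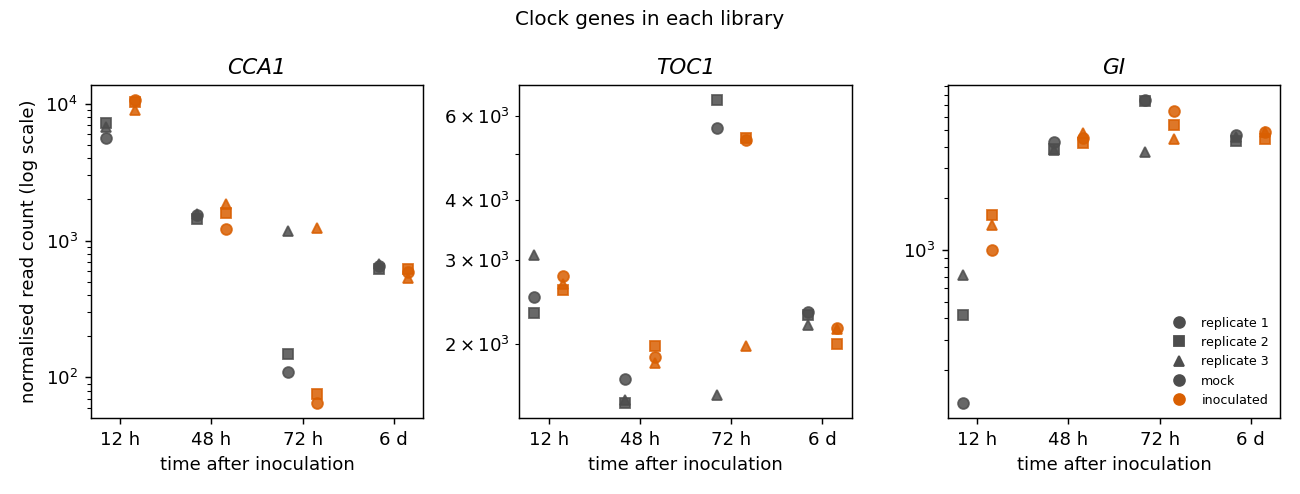
CCA1, TOC1 and GI in each of the 24 libraries, in normalised reads on a log axis.

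At 6 d the division genes as a list rose, after falling at the earlier times. TSO2, a ribonucleotide reductase gene of S phase, went from 1702 ± 118 to 3405 ± 156 (2.00-fold, log2 1.00, SE 0.09, adjusted p = 7.64e-07, n = 3), the sliding clamp gene PCNA1 rose 1.65-fold (log2 0.72, SE 0.13) and the helicase gene MCM2 1.46-fold (log2 0.55, SE 0.10). Of 31 cell cycle genes 15 rose and 0 fell (16 and 0 adjusted over the list alone), median 0.30 (camera adjusted p = 5.35e-08; adjusted p = 0.366 with an estimated correlation). Of 8 root meristem and root cap genes 2 rose and 0 fell (2 and 0 adjusted over the list alone), median 0.36 (adjusted p = 0.0322; adjusted p = 0.436 with an estimated correlation; 0.0705 without mock replicate 3 and 0.0529 without inoculated replicate 2). The largest increases at 6 d included the MATE gene AT2G04070 27.4-fold (log2 4.78, SE 0.77), the peroxidase gene AT1G49570 7.64-fold (log2 2.93, SE 0.33), the glutamate receptor gene GLR2.3 14.6-fold (log2 3.87, SE 0.68) and GMI1 5.75-fold (log2 2.52, SE 0.18).

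The iron and nitrate lists, higher at 12 h, were lower at 6 d. BHLH101, an iron deficiency regulator, went from 71.08 ± 13.2 to 21.36 ± 3.45 (3.22-fold, log2 -1.69, SE 0.20, adjusted p = 8.01e-06, n = 3) and FIT fell 1.65-fold (log2 -0.72, SE 0.14). Of 31 iron genes 8 fell and 0 rose (8 and 0 adjusted over the list alone), median -0.43 (camera adjusted p = 0.00191; adjusted p = 0.506 with an estimated correlation). The nitrate-induced BT1 fell 3.04-fold (log2 -1.60, SE 0.27), UPM1, of the cofactor pathway of nitrite reductase, 1.72-fold, and TGA1, a regulator of nitrate response, 1.38-fold. Of 23 nitrate genes 13 fell and 2 rose (14 and 3 adjusted over the list alone), median -0.38 (adjusted p = 0.000174; adjusted p = 0.366 with an estimated correlation). Of 13 sugar starvation genes 10 fell and 2 rose (11 and 2 adjusted over the list alone), with BT2 2.08-fold and SEN1 3.23-fold lower, median -0.67 (adjusted p = 0.00141; adjusted p = 0.508 with an estimated correlation). Against this, RNS1 was still 4.09-fold higher, and of 27 phosphate genes 6 rose and 2 fell (6 and 2 adjusted over the list alone), the list not passing (adjusted p = 0.159; 0.0203 without mock replicate 3).

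Immune and glucosinolate genes were lower at 6 d. WRKY33, a regulator of camalexin synthesis, fell 1.57-fold (log2 -0.65, SE 0.13), the peroxidase gene PER4 1.95-fold and the chitin receptor gene LYK4 1.49-fold. Of 37 pattern immunity genes 14 fell and 1 rose (15 and 1 adjusted over the list alone), median -0.22 (camera adjusted p = 0.00898; adjusted p = 0.590 with an estimated correlation). CYP83A1, of the aliphatic glucosinolate core, fell from 5084 ± 266 to 1907 ± 254 (2.68-fold, log2 -1.42, SE 0.15, adjusted p = 1.95e-06, n = 3), and 12 of 17 members fell with 0 rising (12 and 0 adjusted over the list alone), median -0.63 (adjusted p = 9.61e-07; adjusted p = 0.366 with an estimated correlation). IGMT1, an indole glucosinolate methyltransferase gene with a near-identical copy, fell 4.15-fold (log2 -2.05, SE 0.21), and the amino acid transporter gene UMAMIT17 4.30-fold (log2 -2.10, SE 0.23). Of 24 indole defence genes 8 fell and 1 rose (10 and 1 adjusted over the list alone). That list did not pass (adjusted p = 0.0628), but passed without mock 6 d replicate 2 (0.0302), inoculated 6 d replicate 2 (0.0102), inoculated 12 h replicate 3 (0.0428) or inoculated 72 h replicate 3 (0.0448).

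Smaller shifts at 6 d were less steady. GH3.3 rose 3.68-fold (log2 1.88, SE 0.25) and IAA19 2.17-fold, and 8 of 25 auxin response genes rose with 2 falling (8 and 3 adjusted over the list alone). The auxin median was 0.15 (camera adjusted p = 0.0458; adjusted p = 0.523 with an estimated correlation), and the list did not pass without mock 6 d replicate 2 (0.0542), inoculated 6 d replicate 2 (0.0642), mock 12 h replicate 2 (0.0509) or inoculated 12 h replicate 1 (0.0527). The sugar exporter gene SWEET12 fell 3.12-fold (log2 -1.64, SE 0.34) and the phloem lectin gene PP2-A1 1.47-fold. Of 8 phloem genes 2 fell and 0 rose (2 and 0 adjusted over the list alone), median -0.21 (adjusted p = 0.0311; adjusted p = 0.307 with an estimated correlation; 0.107 without mock replicate 2 and 0.0535 without inoculated replicate 1). Of 18 suberin genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), median -0.23 (adjusted p = 0.0311; adjusted p = 0.680 with an estimated correlation; 0.230 without mock replicate 3, at a median of -0.14, 0.118 without inoculated replicate 1 and 0.106 with fry). ARR3 and CYP735A2 rose 1.96-fold and 1.66-fold, and 4 of 23 cytokinin genes rose and 4 fell.

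Some lists passed at no time in camera with all libraries. Of 15 auxin synthesis and transport genes 1 rose and 2 fell at 12 h, 0 and 4 at 48 h, 1 and 5 at 72 h, and 2 and 1 at 6 d. That list passed with fry at 48 h (median -0.16, adjusted p = 0.00503) and 72 h (median -0.14, adjusted p = 0.0186). Of 10 heat shock genes 2 rose and 0 fell at 12 h, 3 and 1 at 48 h, with the chaperone gene HSP90.1 at 1.94-fold, 3 and 2 at 72 h, and 0 and 1 at 6 d. Of 20 salicylate genes 2 rose and 0 fell at 12 h, 5 and 3 at 48 h, and 4 and 5 at 6 d, with the glucosyltransferase gene UGT76B1 1.53-fold higher at 12 h and 1.82-fold higher at 48 h. Of 16 clock genes 1 fell at 48 h and 0 passed later (camera adjusted p = 0.470 at 72 h). The p of clock genes rest on a spread pooled over all 24 libraries, including the 72 h groups split in clock state. A difference is thus not excluded: PRR7, picked after its values were seen, was at 4020 to 4383 in mock and 2715 to 2946 in inoculated roots at 6 d. The clock list did pass at 12 h (median 0.38) and 72 h (median -0.32) with a replicate block (0.0105 and 0.0336), without both 72 h libraries numbered 3 (0.0126 and 0.0168) and with fry (0.00655 and 0.0295). No photosynthetic gene passed at 48 h or 72 h and 1 of 29 rose at 6 d. No xylem gene passed at 12 h or 6 d, while 7 of 19 fell at 48 h, with FLA11 1.40-fold lower, and 4 rose and 1 fell at 72 h. The xylem list did pass at 48 h (adjusted p = 0.121 with all libraries) without mock 48 h replicate 3 (0.00999) or inoculated 48 h replicate 2 (0.0464).

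**Figure D4:**
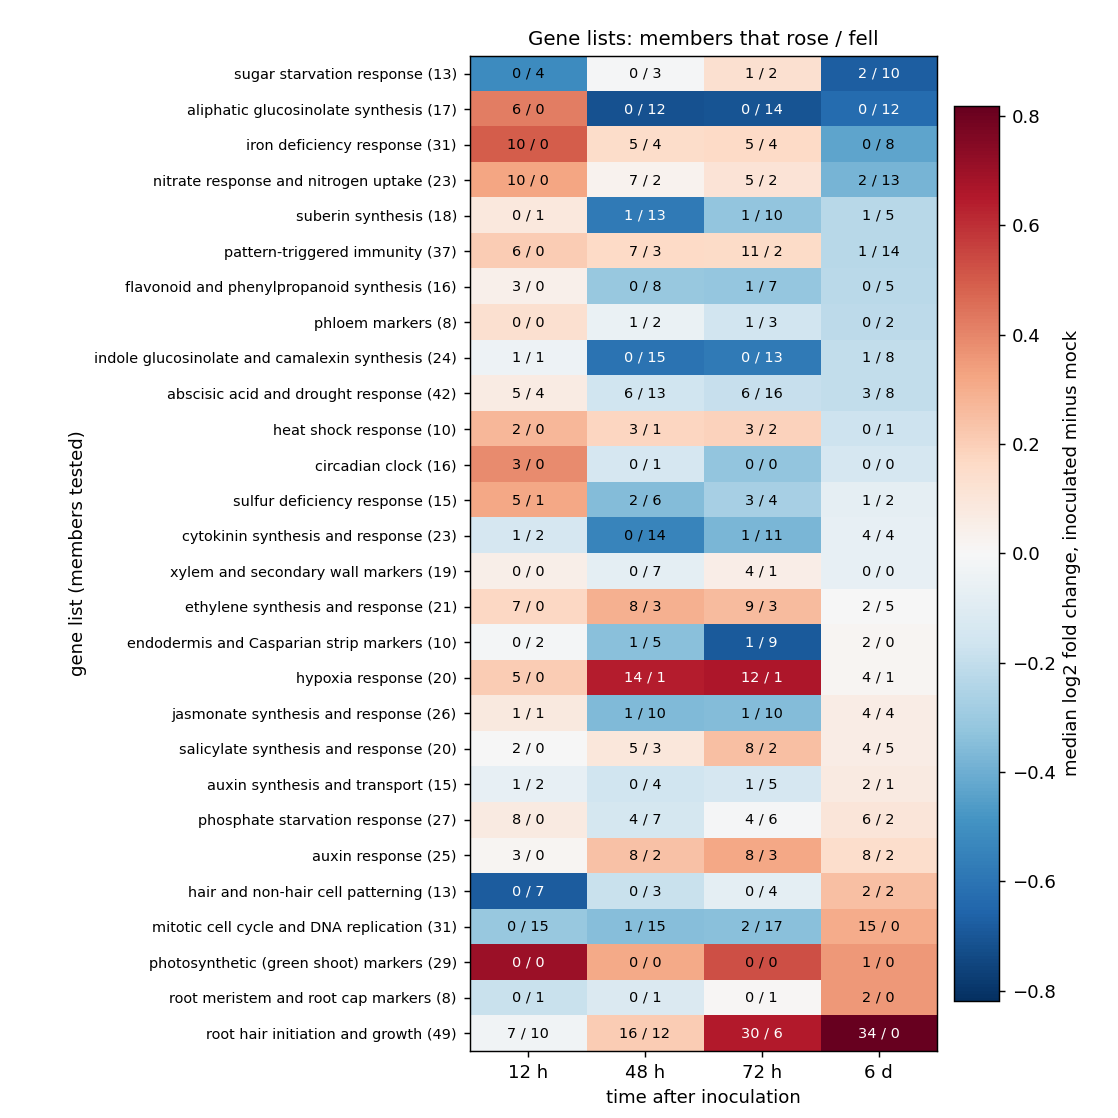
Median log2 fold change of each of the 28 gene lists at each time, inoculated minus mock.

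The response itself changed over time for 6114 genes (joint test, adjusted p under 0.05). The response differed for 4084 genes between 6 d and 48 h and 3328 between 6 d and 72 h, against 1819 between 48 h and 12 h, 1872 between 72 h and 12 h, and 4624 between 6 d and 12 h. The dirigent-like gene AT4G11210 was 2.62-fold lower at 12 h, 4-fold lower at 48 h, 5.71-fold lower at 72 h, and then 1.81-fold higher at 6 d (joint adjusted p = 2.56e-08). BGLU22, a beta-glucosidase gene, was 1.81-fold, 1.75-fold and 1.63-fold lower and then 1.35-fold higher. AT4G33550, a lipid-transfer protein gene, was 2.59-fold, 5-fold, 8.19-fold and 1.5-fold lower, and the sulfotransferase gene ST4B was 1.89-fold lower at 48 h, 1.79-fold lower at 72 h and 1.73-fold higher at 6 d. AT5G62330, so reduced at the first 3 times, did not pass at 6 d (1.08-fold lower, adjusted p = 0.785). Near-identical neighbours of AT4G11210 make its own level uncertain.

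Of lists that passed at both 12 h and 6 d in opposite directions, the median response moved between these times by 0.65 for cell cycle (camera adjusted p = 1.28e-15), -0.69 for nitrate (adjusted p = 2.04e-09), -0.92 for iron (adjusted p = 3.91e-07), -1.12 for aliphatic glucosinolate (adjusted p = 2.81e-09) and -0.41 for pattern immunity (adjusted p = 0.000177). The aliphatic move lay between 12 h and 48 h (-1.13), with 0.08 between 72 h and 6 d (adjusted p = 0.918). None of the moves between 12 h and 6 d passed when the correlation was estimated (adjusted p = 0.160, 0.160, 0.199, 0.222 and 0.358 with an estimated correlation). Genes higher at both 12 h and 6 d numbered 372 against 205.5 by independence (Fisher's exact p = 2.61e-32), and 355 went from lower to higher against 198.4 (Fisher's exact p = 9.08e-30). Genes lower at both numbered 249 against 227.6 (Fisher's exact p = 0.0626). Those that went from higher to lower numbered 190 against 235.8, fewer than by independence. Fisher's test takes genes as independent, which they are not. In all, 310 genes were higher and 185 lower at all 4 times.

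Mock roots also changed with time: 7868 genes differed between the 4 mock groups, and 3637 between 48 h and 12 h, 124 between 72 h and 48 h, and 2592 between 6 d and 72 h. Among them were genes of clock and iron uptake. CCA1 was at 5588, 7260 and 6703 at 12 h, 1527, 1425 and 1571 at 48 h, and 654.1, 619.4 and 674.6 at 6 d, and FRO2 was at 48240, 45250 and 27290, 16980, 15380 and 14120, and 5488, 8170 and 9487. In TOC1, mock 72 h replicates 1 and 2 (5673 and 6492) lay further from 48 h (1501 to 1689) and 6 d (2190 to 2336) than replicate 3 (1564). Age and days on the plate changed together across the mock groups. The labels do not give the hour of harvest, but 12 h, unlike the later times, is not a whole number of days after inoculation. Mock roots at 12 h were in another clock state than at 48 h. GI was at 128 to 717.6 at 12 h and 3840 to 4265 at 48 h, and PRR7 at 57.72 to 159.9 and 2696 to 3041. The comparison of mock groups does not separate these, and a response that differs between times carries the same limit.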

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

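The tests of mature root zone and of library scaling for the root hair list were chosen only after that result had been seen. The others were fixed before their values were computed.

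The response to inoculation differed between times for 6114 genes in the joint limma test. By pair it differed for 1819 genes between 48 h and 12 h, 1872 between 72 h and 12 h, 4624 between 6 d and 12 h, 2 between 72 h and 48 h, 4084 between 6 d and 48 h, and 3328 between 6 d and 72 h. With camera at its preset correlation, lists whose response differed numbered 14, 17, 11, 10, 16 and 13 for the same pairs in the same order, and 0 with the correlation estimated from the data. The lists that passed at both 12 h and 6 d in opposite directions moved between these times by medians of 0.65 for cell cycle, -0.69 for nitrate, -0.92 for iron, -1.12 for aliphatic glucosinolate and -0.41 for pattern immunity. Root hair moved by 0.86 and hair cell patterning by 0.72.

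The genes whose response differed most were AT4G11210, ZW9, BGLU22 and AT4G11190 (joint adjusted p = 2.56e-08 for each), AT4G33550 (7.46e-08), AT4G25250 (1.29e-07), ST4B (1.41e-07), AT5G62330 (1.56e-07), CEP2 (1.79e-07) and AT5G04120 (3.50e-07). Most went from lower at the middle times to higher at 6 d: AT4G11190 from 2.16-fold lower at 48 h to 2.68-fold higher, and AT5G04120, a phosphoglycerate mutase family gene, from 3.33-fold lower at 72 h to 7.54-fold higher. AT4G11190 and AT4G11210 are close dirigent-like copies, so the share of each is uncertain.

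The libraries were regrouped to see how many calls other groupings give. For the tests between times 100 splits were drawn, within each time for the response and across times among the 12 mock libraries for the mock test. The real labels gave the highest count in each, 1 of 100. The joint test called 6114 genes against at most 3368 in any other split, the list differences 81 against 72, and the mock time test 7868 against 6433. Chance is argued against for the mock count. For the joint test and the list differences the splits cannot decide, because they mix treatments within a time. Their reference is no response at any time, not an equal response at all times. They also ignore the replicate numbers taken to pair at 72 h, and other splits came close for the lists. Within a time there are 10 splits of 6 libraries, too few for a share under 0.05. At 12 h the real split called 3683 genes and the highest other 2 (1 of 10 as high), and 11 lists against 13 (3 of 10). At 48 h it called 8151 genes against 1 (1 of 10) and 9 lists against 16 (6 of 10). At 72 h it called 7930 genes against 560 (1 of 10) and 10 lists against 11 (3 of 10), and at 6 d 5493 genes against 0 (1 of 10) and 11 lists against 12 (3 of 10). At 72 h 6 of the other splits kept 2 pairs of the same number together, and they called 560, 293, 183, 0, 0 and 0 genes. The 3 that called most put both libraries numbered 3 on one side, as did 1 that called 0. The splits that parted all 3 pairs, apart from the real one, called at most 1. The number of lists passing at a time was thus no higher than other splits gave, while the number of genes was.

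The 72 h libraries numbered 3 stood apart from replicates 1 and 2 of both treatments in clock and iron genes. In clock state it was replicates 1 and 2 that lay away from 48 h and 6 d. The clock gene ELF4, named after its values were seen, was at 3833 and 4064 in mock 72 h replicates 1 and 2. It was at 261.7 in replicate 3, 246 to 284.6 in mock at 48 h and 268.6 to 330 at 6 d. Whether the libraries numbered 3 were mislabelled 48 h libraries was tested on a scale from 48 h at 0 to 6 d at 1. The one nearer to 48 h lay 0.174 above the highest 48 h library of its treatment, where those libraries spanned 0.099. The mock one lay 0.296 above, with a span of 0.071. Both exceeded the limit set beforehand against mislabelling, but the test cannot decide. The same 48 h libraries chose the genes and set the scale, so another 48 h library could lie outside their span. Green markers also fell along the scale in mock roots, from 0.279 to 0.536 at 48 h to -0.78 to -0.534 at 6 d. A 48 h library low in green tissue could thus lie toward 6 d. Of the differences of 9 further clock genes, 18 of 18 had the sign of midday against evening. Clock genes change together, so this count adds little to the split of CCA1 and TOC1 already seen. Harvest at another hour remains a candidate explanation, and ELF4 would place the other hour with replicates 1 and 2. The libraries numbered 3 were also lower in green markers, with photosynthetic means of -1.638 and -0.955 against -0.192 to 1.206 in the other 72 h libraries. A harvest with less green tissue stays open beside another hour and was not tested. Either may contribute to the 1395 genes that differed more than 2-fold in mock, of which 606 did so in both treatments with the same sign. Harvest times in the laboratory record would help to separate these.

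The root hair list rose at 6 d by a mean of 0.814, with 34 of 49 genes higher and 0 lower. The highest mean of the endodermis, suberin, xylem and phloem lists was 0.142, so these mature tissue lists did not rise to the same extent. They cannot exclude a harvest richer in mature root, since inoculated roots may express them less per cell. The endodermis and suberin lists were lower at 72 h (medians -0.69 and -0.33). The suberin and phloem lists passed as lower in camera at 6 d (medians -0.23 and -0.21). With TMM scaling the list median stood 0.83 above the median of all genes. That difference cannot test scaling, because a scaling moves the genes of a library alike and cancels from it. The median of all genes at 6 d was -0.00944 with the deposited scaling and -0.00776 with TMM, so these scalings hardly differed. A hypothesis left open is that inoculated roots carried more or longer hair cells, which may raise these transcripts with no change per cell. Counts of hairs per root length, or reporters of XTH26 and PRX44 in single cells, would separate more or longer hairs from a change per cell.

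The aliphatic glucosinolate list rose at 12 h (median 0.42) and then fell. Part of the rise rested on mock replicate 1 at 12 h, which was low in green markers and in this list. Without it the median was 0.21 (adjusted p = 0.0174, 5 genes higher), and with the photosynthetic mean as a covariate it was 0.31 (5 genes higher). Green tissue carried into some libraries, that library alone, or an early response could each give this, and these values do not decide between them.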

How the results depend on the processing

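Every alternative with TMM scaling, another pseudocount, a block within the 6 libraries of a time, both 72 h libraries numbered 3 left out, or the green marker covariate was chosen only after the result had been seen. The rest were fixed before.

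At 12 h and 72 h gene counts depended most on how the spread was estimated. With limma on only the 6 libraries of 12 h, 551 genes were higher and 671 lower, in place of 1874 and 1809, and with a replicate block on those 6 libraries 580 and 612. At 72 h the 6 libraries alone gave 2424 higher and 2581 lower, in place of 3813 and 4117. With a replicate block on those 6 libraries they were 3518 and 3796. At the other times the 6 libraries alone called more: 4362 and 4499 at 48 h, in place of 3995 and 4156, and 3412 and 3941 at 6 d, in place of 2558 and 2935. Replicates lay further apart at 12 h and 72 h than at the other times. The highest chi-square per gene between replicates was 34.24 at 12 h and 46.67 at 72 h, against 16.94 at 48 h and 13.24 at 6 d. A spread pooled over all times may thus be too small for 12 h, where the main counts may be too high. The cause of the wider spread was not tested. With the block in the fit of all 24 libraries, counts were 2072 and 1935 at 12 h, 4134 and 4376 at 48 h, 3995 and 4321 at 72 h, and 2669 and 3289 at 6 d.

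Leaving out 1 library at a time, genes higher ranged from 1118 to 2185 at 12 h, 3223 to 4167 at 48 h, 3066 to 4004 at 72 h and 1629 to 2822 at 6 d. Genes lower ranged from 1071 to 2132, 3322 to 4358, 3340 to 4276 and 1978 to 3189. Inoculated replicate 1 gave the lowest counts at 12 h and at 6 d, and the cause was not tested. The joint test of the response ranged from 4928 to 6876, the mock time test from 6511 to 8639, lists at each time from 37 to 45 and lists between times from 70 to 84.

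Tools mattered less. DESeq2 on recovered reads called 2189 and 1979 genes at 12 h, 4115 and 4367 at 48 h, 4005 and 4251 at 72 h, and 2823 and 3161 at 6 d. Of calls at 6 d 46.6% were increases with the deposited scaling, 46.7% in limma with TMM scaling, 46.8% in edgeR with RLE scaling, 47.2% in DESeq2 and 50.8% in edgeR with TMM scaling.

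Gene lists depended on the correlation between members. With camera and an estimated correlation 0 lists passed at each time, in place of 41, and 0 between times, in place of 81, though 13 and 32 were under 0.05 before adjustment and fry passed 38 of the 41. The root hair medians were unchanged, 0.65 at 72 h and 0.82 at 6 d, but with an estimated correlation their adjusted p were 0.576 and 0.307. Fry also passed 14 others, 52 in all. At 12 h it passed circadian clock (0.00655). At 48 h it passed auxin synthesis and transport (0.00503), endodermis (0.0396), hair cell patterning (0.00124) and ethylene (0.0103). At 72 h it passed abscisic acid and drought (median -0.19, adjusted p = 0.0315), auxin synthesis and transport (0.0186), circadian clock (0.0295), hair cell patterning (8.91e-05), ethylene (0.00503), flavonoids (0.0301) and salicylate (0.0114), and at 6 d flavonoids (0.0315) and indole defence (0.0382). A block within time added 8 lists and lost 0: at 12 h circadian clock (0.0105) and photosynthetic markers (0.0196), at 48 h endodermis (0.0203), at 72 h circadian clock (0.0336), nitrate (0.0455), pattern immunity (0.0414) and salicylate (0.0403), and at 6 d flavonoids (0.0483). Without both 72 h libraries numbered 3 the circadian clock list passed at 12 h (0.0126) and 72 h (0.0168).

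At 48 h the root hair list passed without inoculated replicate 3 (median 0.30, adjusted p = 0.0232), without mock 72 h replicate 3 (0.21, 0.0449) and without both 72 h libraries numbered 3 (0.21, 0.0461). Its median over the libraries left out ranged from 0.17 to 0.30. The photosynthetic median at 12 h reversed to -0.40 without mock replicate 1 and ranged up to 1.48 without mock replicate 2, since mock replicate 1 held few green transcripts.

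Named genes were followed at 487 combinations of gene and time, which include members that had not passed. Of those that passed, 0 reversed in any alternative. Calls lost numbered 4 with edgeR and TMM scaling, 2 with DESeq2, 14 with no filter and 42 with only the 6 libraries of a time, which gained 5. At 12 h leaving out 1 library lost 7 to 22 calls, the most without inoculated replicate 1.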

Other observations

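The mitochondrial stress and triterpene lists below were written only after the largest changes had been seen, so counts, medians and list tests are given for the members not seen then.

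Genes that respond to mitochondrial dysfunction rose from 12 h to 72 h. UGT74E2, an auxin glucosyltransferase gene of this response, went from 2325 to 7996 normalised reads at 48 h (log2 1.78, SE 0.12, limma adjusted p = 3.11e-09, n = 3 libraries per group). The alternative oxidase gene AOX1A rose from 2973 to 5078 (log2 0.77, SE 0.14), the membrane-bound regulator gene NAC13 from 418.4 to 995.6 (log2 1.24, SE 0.14) and BCS1 from 259.4 to 949.7 (log2 1.86, SE 0.23). Of the 13 tested members not seen before, 10 rose at 12 h, 9 at 48 h, 10 at 72 h and 3 at 6 d, and 0 fell at any time. Medians were 0.71, 0.94, 1.06 and 0.34. The smaller of the 48 h and 72 h medians, 0.94, was above the 0.5 set beforehand for a response of the group. Camera with an estimated correlation passed it at no time (adjusted p = 0.0724, 0.0731, 0.0724 and 0.242 over the 8 tests of both lists).

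Genes of the thalianol and marneral clusters, which make root triterpenes, fell at 48 h and 72 h and did not pass at 6 d. THAS1, which makes thalianol and was among the genes seen first, went from 19100 to 5410 at 48 h (log2 -1.83, SE 0.16, adjusted p = 3.48e-08, n = 3) and from 26850 to 9778 at 72 h, and was at 20100 and 20750 at 6 d (adjusted p = 0.851). Its cluster neighbours CYP708A2 (12970 to 4345), CYP705A5 (18090 to 5534) and AT5G47980 (1316 to 289.5) fell at 48 h, as did CYP705A12 (971.1 to 180.5) and CYP71A16 (3133 to 1182) beside MRN1 in the marneral cluster. Of 13 members not seen before, 1 rose and 3 fell at 12 h, 0 and 8 at 48 h, 2 and 9 at 72 h, and 4 and 1 at 6 d, with medians of -0.25, -0.72, -0.78 and 0.25. The weaker of the 48 h and 72 h medians, -0.72, was beyond the -0.5 set beforehand. Camera with an estimated correlation passed it at no time (adjusted p = 0.242, 0.0724, 0.0724 and 0.189 over the same 8 tests). The members not seen before include the cluster neighbours of THAS1 and MRN1, which had prompted the list. The median is thus not independent of that choice, and it does not show a fall beyond the thalianol and marneral clusters. In the arabidiol and baruol clusters members differed. PEN1 fell at 48 h (1505 to 947.2, log2 -0.67, limma adjusted p = 5e-05) and 72 h (1496 to 1067, log2 -0.50, limma adjusted p = 0.000943). CYP705A1, CYP705A2, CYP705A3 and BARS1 did not fall at these times, but CYP705A3 and BARS1 were at only 0.97 to 10.64 in mock roots. At 72 h CYP705A3 rose from 0.97 to 34.26 (log2 4.26, SE 0.80) and CYP705A2 from 60.97 to 127.9 (log2 1.04, SE 0.29). CYP716A1 was lower at 6 d (log2 -0.67, adjusted p = 0.0304).

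These observations carry hypotheses that the data do not settle. Mitochondrial stress genes rose (smaller median 0.94) in the same hours as the hypoxia list, which may reflect bacterial oxygen use near the root, a bacterial product that acts on respiration, or retrograde signals from another stress. Oxygen profiles along inoculated roots, and AOX1A reporters in roots given culture filtrate, would tell these apart. Root triterpenes are known to shape the bacteria that live on roots, so lower cluster genes (weaker median -0.72) might alter colonisation. Measuring thalianol and marneral, and counting bacteria on mutants in THAS1 and MRN1, would test this.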
